A study of Mus musculus with 8 samples.

How the data were processed

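The series measured polyadenylated RNA of the left ventricle of C57BL/6J mice after cardiac ischemia-reperfusion, in which the left anterior descending coronary artery is tied off and then released. Per the labels, mice received 2 intramyocardial injections of 10 µl of a UPy-PEG hydrogel, a supramolecular polymer gel used as a drug depot, and hearts were taken 3 days after injury. In 1 group of 4 libraries the gel held no drug, and in the other group of 4 it held antimiR-195, an oligonucleotide inhibitor of the microRNA miR-195. The groups were taken from the drug field of the labels. Each library has its own title, but no label states that the 8 libraries came from 8 separate animals, so the p-values measure the spread between these libraries. Replicates were numbered within each group in accession order, so a number pairs nothing across the groups.

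Per the labels' protocols, RNA was isolated with TRIzol and libraries were made with a TruSeq stranded mRNA kit. The submitters' processing notes name STAR, HTSeq, DESeq and the GRCm38 build, without versions. The annotation release, the strand setting of the counting and the read length are not given in the sources used here. The deposited values are whole-number HTSeq counts per Ensembl gene, 1 set per library and again as a table of the whole series. Both held the same counts, with 0 differing cells, so the alternative of using the series table was not run. The authors also deposited RPKM values, and the gene length they imply together with the counts was the same in all libraries, with a largest relative spread of 4.1e-07. RPKM values entered alternatives and gave the gene lengths, and no count test was run on them.

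Counts covered 38293 gene identifiers, of which 36345 had a name in the GENCODE mouse release M21 annotation of GRCm38. Unnamed identifiers held at most 0.175% of the gene counts of a library. The HTSeq lines that name no gene were left out of library sizes and tests. Reads outside annotated genes made up 6.38% to 7.55% of the uniquely aligned reads of a library, and reads that could belong to more than 1 gene 0.772% to 1.05%. The line for alignments to more than 1 place held 42.1% to 47.8% of all lines, highest in antimiR-195 replicate 2. Genes with near-identical copies are therefore uncertain, and so are overlapping and antisense genes, since the strand setting is not known.

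Total gene counts ranged from 16872968 to 22751753 per library. Genes with enough counts (filterByExpr) were kept, 13972 in all, and scaled with TMM factors between 0.953 and 1.04. The main test was edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) of antimiR-195 against drug-free hydrogel over all 8 libraries without covariates. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Fold changes are given as log2 of antimiR-195 over hydrogel ± their standard error, and levels as CPM, gene counts scaled by the normalized library size, computed from the deposited counts, with the SD over 4 libraries. Tests are two-sided. For values per library an exact permutation test over the 70 assignments of 4 of the 8 libraries was used, whose smallest possible p is 0.0286.

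Before the data were examined, 30 gene lists with 468 members were fixed, of which 466 were found in the files and 417 entries passed the filter. Each list with at least 5 tested members, 27 in all, was compared with the other genes by camera (limma 3.58.1) on log2 CPM (prior count 2) with a preset correlation of 0.01. Camera with an estimated correlation, fry and the exact permutation test of the list's mean z score per library were set beside it. The lists cover the literature targets of the miR-15 and miR-195 family, cell cycle, cardiomyocyte, metabolic, matrix, immune and other cell type genes, stress programmes and interferon response. Named genes were fixed by a rule: the 10 genes per direction with the smallest p and a mean log2 CPM of at least 0 where fewer pass the threshold, the 3 members of each list with the smallest p, 8 targets of miR-195, and Xist and Ddx3y. Some genes that met the rule are not reported here. Other list members named, and genes seen in single libraries, were chosen after their values were seen.

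For the seed site analysis, 3′ UTRs were taken from the M21 annotation and transcripts, using the transcript with the longest 3′ UTR of at least 50 bases per protein-coding gene. A gene had a site when its UTR held a match to the miR-195 seed of 7 bases or more, in the classes known as 7mer-A1, 7mer-m8 and 8mer. The log2 difference between groups was regressed on site presence, log2 UTR length, UTR GC and mean log2 CPM over 12860 genes, and the p came from the 70 assignments of the libraries. The tissue composition score of a library was the mean z score of the matrix and macrophage lists minus that of the sarcomere list.

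The edgeR, DESeq2 and limma-voom tests, camera with the preset correlation, the seed site regression and the removal of the length trend were tested on simulated or planted changes; the other procedures were not. For the comparison of antimiR-195 with hydrogel, counts of 13972 genes were simulated with 50 genes changed at each of 4 fold sizes. The edgeR quasi-likelihood test recovered 0 of 50 genes changed 1.25-fold, 6 changed 1.5-fold, 28 changed 2-fold and 50 changed 4-fold, with 7 false calls. A list of 20 genes shifted by 0.3 on the log2 scale was called by camera at adjusted p = 3.11e-07, with 0 of the other lists called. The simulated genes varied independently of each other and no library was set apart. The simulation therefore did not test whether the preset correlation suits the real libraries. A seed site shift of 0.05 added to the real libraries was recovered as 0.05 at the smallest possible permutation p of 0.0286. The regression itself fixes the size recovered from such an addition, so only the p was informative.

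Alternatives fixed before the data were examined were DESeq2 size factors and upper-quartile factors, no filter and a minimum of 10 counts in every library, leaving out each library in turn, the tissue composition score or 1 surrogate variable (sva 3.50.0) as a covariate, DESeq2 1.42.0, edgeR's likelihood ratio test, limma-voom with sample quality weights, limma-trend on log2(RPKM + 0.1) and log2(RPKM + 1), camera on ranks, and other definitions of the seed site. Removal of the trend of each library with gene length, by lowess with a span of 0.3, was chosen after seeing the data. Figures and seed regressions used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.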

Results

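The data set comprised 8 libraries of left ventricular polyadenylated RNA, 4 from ventricles injected with drug-free hydrogel and 4 from ventricles injected with hydrogel carrying antimiR-195. Total gene counts ranged from 16872968 in antimiR-195 replicate 3 to 22751753 in hydrogel replicate 3. All libraries had a male pattern, with 0 to 2 counts of Xist and Ddx3y at 67.6 ± 7.88 CPM in the hydrogel group and 71.1 ± 8.99 CPM in the antimiR-195 group (SD, n = 4 each). Correlations of log2 CPM across genes were 0.944 to 0.970 between antimiR-195 replicate 2 and the other libraries and 0.978 to 0.991 between all other pairs, so no library was a copy of another.

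The comparison of antimiR-195 with drug-free hydrogel asked which transcripts differed 3 days after injury when the gel carried the inhibitor. No gene passed the threshold. Tnf, which encodes the inflammatory cytokine tumour necrosis factor, was 1.46 ± 0.515 CPM with antimiR-195 and 0.681 ± 0.101 CPM without (SD, n = 4), a log2 fold change of 1.10 ± 0.30. F13a1, which encodes coagulation factor XIII A and is carried by resident macrophages, was 85.7 ± 6.36 against 111 ± 5.44 CPM, a log2 fold change of -0.37 ± 0.10. Elovl7, a fatty acid elongase, had the largest difference of the named genes at -2.57 ± 0.68, with 0.295 ± 0.17 against 1.78 ± 1.41 CPM. Each of these 3 genes had all antimiR-195 libraries on one side of all hydrogel libraries, and the adjusted p of each was 0.9999 in edgeR's quasi-likelihood test. For Elovl7 the gap was narrow, with 0.547 CPM in antimiR-195 replicate 2 and 0.555 CPM in hydrogel replicate 4. Its hydrogel mean rested on hydrogel replicates 2 and 3, at 3.18 and 2.82 CPM. For Tnf the nearest libraries were antimiR-195 replicate 3 at 1.02 CPM and hydrogel replicate 2 at 0.831 CPM.

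Of 13972 genes tested, 0 were higher and 0 lower at adjusted p below 0.05 in edgeR's quasi-likelihood test, and the smallest adjusted p was 0.9999. At an unadjusted p below 0.05 there were 178 genes, 1.27% of those tested, 116 higher and 62 lower. That share was below the 0.05 that evenly spread p-values would give. DESeq2 called 0 genes with 237 at unadjusted p below 0.05, edgeR's likelihood ratio test 0 with 199, limma-voom with quality weights 0 with 333, and limma-trend on log2(RPKM + 0.1) 0 with 180. The groups did not overlap in 150 genes, 1.07% of those tested, where chance gives 2.86%. The biological coefficient of variation was 19.1%. For the 13256 genes with a mean log2 CPM of at least 0, the median standard error of a log2 fold change was 0.17 and the median half-width of its 95% confidence interval was 0.37.

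Other genes of smallest p on the higher side included Baalc, Dio3, Arsi, Cemip, Cxcr6, Snai1 and Crct1. Snai1, a transcription factor of epithelial-mesenchymal transition, was 10.4 ± 2.40 against 7.26 ± 0.532 CPM, a log2 fold change of 0.52 ± 0.17. Cxcr6, a chemokine receptor of T cells, had a log2 fold change of 1.19 ± 0.38, or 0.69 without antimiR-195 replicate 2, and Dio3, the enzyme that inactivates thyroid hormone, one of 0.83 ± 0.25. On the lower side they were Phf21b, Fcgr2b, Lyz1, Igsf23, Hpgd, Omd, Plekhb1 and Gltp. Fcgr2b, the inhibitory Fc receptor of macrophages and B cells, was 37.0 ± 1.89 against 46.5 ± 3.49 CPM, a log2 fold change of -0.33 ± 0.10. Hpgd, which degrades prostaglandins, had a log2 fold change of -0.40 ± 0.13. In GRCm38, Tnf lies on chromosome 17 at 35199381 to 35202007, F13a1 on chromosome 13 at 36867178 to 37050244, and Fcgr2b on chromosome 1 at 170958617 to 170976547. None of these genes passed the threshold.

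Inhibition of miR-195 would act on transcripts with miR-195 sites, and 32 literature targets of the miR-15 and miR-195 family were fixed as a list. Of the 32 targets, 19 had a positive and 13 a negative log2 fold change, with a median of 0.02, and 0 passed the threshold. Cdk6, a kinase of the G1 phase, was 3.25 ± 0.335 against 2.26 ± 0.404 CPM (SD, n = 4), a log2 fold change of 0.53 ± 0.19, with every antimiR-195 library above every hydrogel library. The cell cycle targets Ccnd1 at 0.21 ± 0.18 and Chek1 at 0.31 ± 0.27 did not pass, nor did Wee1, a kinase that delays mitosis, at -0.41 ± 0.43. The survival gene Bcl2 was at 0.02 ± 0.18, the angiogenic factor Vegfa at -0.10 ± 0.23, the metabolic kinase Pdk4 at -0.37 ± 0.37 and Sgk1 at -0.09 ± 0.17. These values moved with single libraries: without antimiR-195 replicate 2, Ccnd1 was at -0.01, Wee1 at -0.08, Bcl2 at 0.12, Vegfa at 0.08 and Sgk1 at -0.01, without antimiR-195 replicate 1 Chek1 was at 0.11, without antimiR-195 replicate 3 Bcl2 was at -0.14, and without hydrogel replicate 2 Pdk4 was at 0.03. Other libraries moved them the other way. Wee1 was at -0.78 without antimiR-195 replicate 4, Pdk4 at -0.65 without antimiR-195 replicate 1 and Vegfa at -0.25 without antimiR-195 replicate 3. Sgk1 was at -0.22 without hydrogel replicate 1 and Chek1 at 0.52 without hydrogel replicate 4. No target passed when p was adjusted over the list alone, where Cdk6 had an adjusted p of 0.67 in edgeR's quasi-likelihood test. Camera gave the list an adjusted p of 0.52, and the exact permutation test of its mean z score gave p = 0.886. The precursor of miR-195, Mir195a, on chromosome 11 at 70235042 to 70235135, had 0 to 2 counts per library, so polyadenylated RNA gave no measure of the microRNA itself.

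Transcripts with a miR-195 seed match were measured as a class. Of 12860 genes with an annotated 3′ UTR, 3667, or 28.5%, held at least 1 site, among them 28 of the 32 literature targets. With UTR length, GC and expression level in the model, genes with a site were shifted by 0.00396 on the log2 scale with antimiR-195, and the exact permutation test over libraries gave p = 0.6. Shifts from -0.01 to 0.02 were not excluded by that test. Of 500 control words, 279 gave a shift at least as large in either direction. Without covariates the median log2 fold change was -0.02 in the genes with a site and 0.00 in those without, and the site genes had a median UTR length of 2289 bases against 906.

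**Figure D1:**
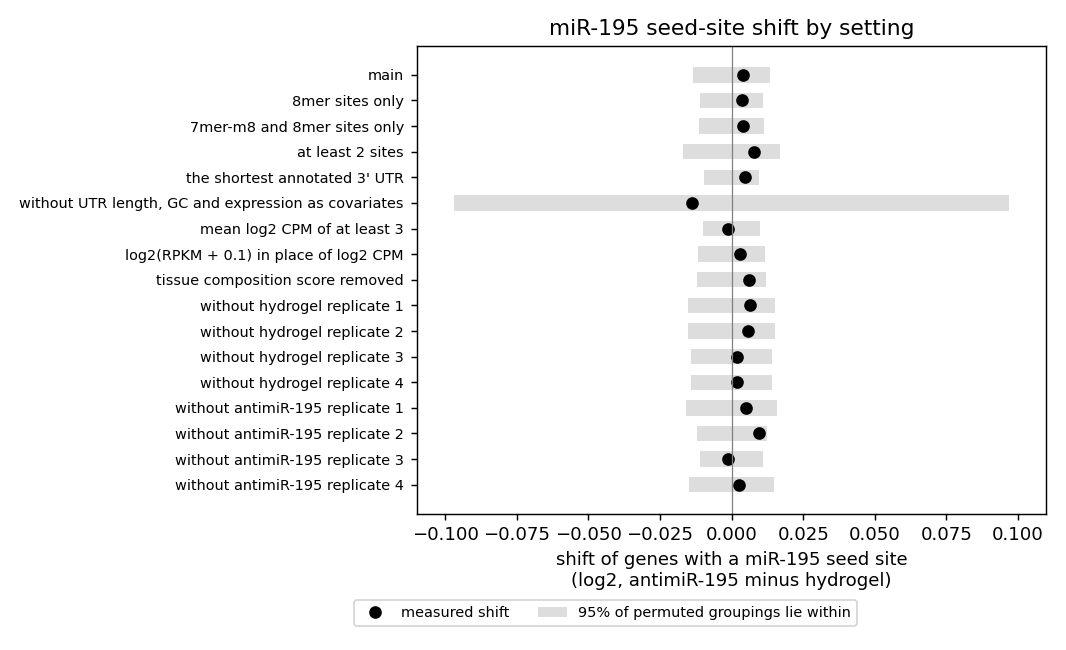
Shift of genes with a miR-195 seed site in log2 units (x axis, antimiR-195 minus hydrogel) for the main model and each alternative (y axis). Points are measured shifts and grey bars span the size that 95% of permuted groupings stay within; every point lies inside its bar.

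Matrix, cell division and interferon genes lay higher with antimiR-195 when each list was set against all other genes with a preset correlation. For each of the 4 lists the adjusted p = 0.597 with an estimated correlation, so none of these camera calls held, and the exact permutation tests of their mean z scores gave p = 0.114 to 0.314. The extracellular matrix and myofibroblast list had 23 of 24 members with a positive log2 fold change and a median of 0.28, led by Tnc at 0.72 ± 0.28, a matrix protein of injured myocardium, and by Timp1 at 0.78 ± 0.38. All 18 interferon response genes were positive, with a median of 0.36, including the antiviral genes Ifi44 at 0.60 ± 0.25 and Mx1 at 0.54 ± 0.23. Among DNA replication genes 19 of 22 were positive, with a median of 0.35, and Cdc45 at 0.55 ± 0.21. Among mitosis genes 23 of 24 were positive, with a median of 0.29, and Ccnb1 at 0.60 ± 0.24, while Cenpf was at -0.38 ± 0.13. No member of these lists passed the threshold over all genes, and 0 passed when adjusted over the list alone.

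Camera with the preset correlation gave adjusted p = 1.64e-09 for the matrix list, 2.08e-09 for interferon response, 4.82e-08 for DNA replication and 8.88e-08 for mitosis. With an estimated correlation the adjusted p = 0.597 for each, and the exact permutation tests gave p = 0.257, 0.114, 0.229 and 0.314 in the same order. AntimiR-195 replicate 2 had the highest list mean of all 8 libraries in each of the 4 lists. Without it, the adjusted p of camera was 4.55e-04 for the matrix list, 0.00126 for interferon response, 0.0089 for DNA replication and 0.0181 for mitosis. Their medians without it were 0.14, 0.11, 0.14 and 0.10, and Tnc was at 0.48, Timp1 at 0.21, Ifi44 at 0.37 and Cdc45 at 0.32. The matrix and mitosis medians were 0.11 and 0.13 without hydrogel replicate 3, and 0.47 and 0.45 without hydrogel replicate 4.

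Inflammatory cytokine, cardiac stress and B cell genes were also called higher by camera with the preset correlation, but adjusted p = 0.597 with an estimated correlation for each, so none of these calls held. Of 22 cytokine and chemokine genes 16 were positive, with a median of 0.35, among them the monocyte chemokines Ccl2 at 0.49 ± 0.21 and Ccl7 at 0.73 ± 0.32. The acute phase gene Saa3 was at -0.89 ± 0.43. Of 18 cardiac stress and fetal programme genes 17 were positive, with a median of 0.15; Acta1, fetal skeletal actin, was at 0.62 ± 0.28 and Myh7, the fetal myosin, at -0.56 ± 0.36. Of 5 tested B cell genes 4 were positive, with a median of 0.38, including the light chain gene Igkc at 0.50 ± 0.24. The adjusted p of camera with the preset correlation was 4.40e-04, 0.00353 and 0.0454 for these lists. AntimiR-195 replicate 2 had the highest mean of all 8 libraries in each of the 3 lists, and without it the 3 calls were lost, at adjusted p = 0.279, 0.575 and 0.661, with medians of 0.06, 0.05 and 0.24. Without it Ccl2 was at 0.25, Ccl7 at 0.28, Acta1 at 0.37 and Igkc at 0.32, and Myh7 was at -0.10 without hydrogel replicate 1. The stress call was also lost without hydrogel replicate 2 (adjusted p = 0.0773) or hydrogel replicate 3 (0.0743, median 0.09), and the B cell call without hydrogel replicate 1 (0.185), hydrogel replicate 3 (0.0795, median 0.15) or antimiR-195 replicate 4 (0.114). The stress median was 0.23 without hydrogel replicate 1 and 0.27 without antimiR-195 replicate 4. Adjusted over the list alone, 0 of their members passed.

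Genes of resident cardiac macrophages lay lower with antimiR-195. Camera gave adjusted p = 2.01e-08 with the preset correlation, and adjusted p = 0.083 with an estimated correlation, so the call did not hold. Of 10 members 9 had a negative log2 fold change, with a median of -0.40: F13a1 at -0.37 ± 0.10, the complement receptor Vsig4 at -0.53 ± 0.21, the hyaluronan receptor Lyve1 at -0.42 ± 0.19 and the phosphatidylserine receptor Timd4 at -0.61 ± 0.32. The exception was Cbr2 at 0.06 ± 0.17. Lyve1 was at -0.26 without antimiR-195 replicate 2. The mean log2 CPM of the list was lower in all 4 antimiR-195 libraries than in all 4 hydrogel libraries, and the group difference was -0.34 on the log2 scale. The fry test of limma, a rotation test rather than an exact one, gave p = 0.00649 and, adjusted over the 27 lists, 0.175. The exact permutation test of the mean z score gave p = 0.0286, the smallest it can give, and 0.771 when adjusted over the lists. F13a1 passed when adjusted over the list alone, at adjusted p = 0.0419 in edgeR's quasi-likelihood test, and no other member of any list did. The broader list of macrophage and monocyte genes had 10 positive and 10 negative members, a median of 0.01 and a camera adjusted p of 0.453, with Ccr2 at -0.32 ± 0.13, Csf1r at -0.20 ± 0.11 and Ly6c2 at 0.84 ± 0.38. Without antimiR-195 replicate 2 its median was -0.21 and Ly6c2 was at 0.47. Camera with the preset correlation called this list lower without antimiR-195 replicate 2 (adjusted p = 3.70e-05), without hydrogel replicate 3 (0.0154), with the composition score (0.00143) or 1 surrogate variable (0.0230) as a covariate, and with the length trend removed and antimiR-195 replicate 2 left out (2.31e-04). The composition score is partly built from this same list, so the call with it as a covariate is not independent evidence. Over its 18 alternatives the adjusted p ranged from 3.70e-05 to 0.894, with adjusted p = 0.867 with an estimated correlation over all libraries, and the direction was up without hydrogel replicate 4 (0.265) or antimiR-195 replicate 3 (0.670).

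**Figure D2:**
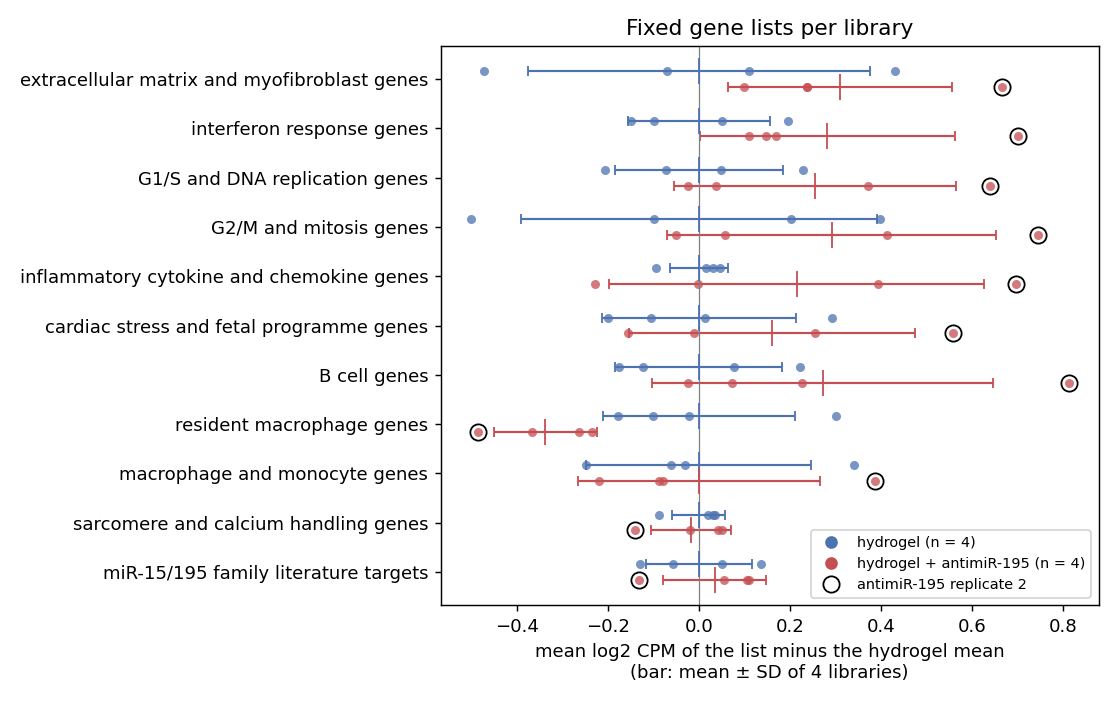
Mean log2 CPM of 11 fixed gene lists in each library, relative to the mean of the hydrogel libraries (x axis), with bars for the mean ± SD of 4 libraries per group. The antimiR-195 libraries lie below the hydrogel libraries in the resident macrophage list, and the circled antimiR-195 replicate 2 is the highest library in the upper 7 lists.

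The remaining lists were not called with all 8 libraries in the main test, but some were without 1 library. Cardiomyocyte sarcomere and calcium handling genes had a median of 0.02 over 18 members and an adjusted p of 0.794, with Mybpc3 at 0.20 ± 0.14 and the calcium pump regulator Pln at -0.16 ± 0.16, or -0.07 without antimiR-195 replicate 2. Fatty acid oxidation genes had 17 of 23 members negative, a median of -0.08 and an adjusted p of 0.0566. These genes had a median of -0.02 without hydrogel replicate 3 and -0.14 without hydrogel replicate 4. They were called lower without hydrogel replicate 4 (adjusted p = 1.12e-05) and without antimiR-195 replicate 1 (0.00359), and with camera on ranks (0.0276), 1 surrogate variable (0.0489) or the length trend removed (0.0204), in a range up to 0.908 over the alternatives, with adjusted p = 0.834 with an estimated correlation. Nuclear oxidative phosphorylation genes had a median of -0.05 with an adjusted p of 0.312. They were called lower without antimiR-195 replicate 2 (adjusted p = 0.00126), without hydrogel replicate 4 (0.00102) and with 1 surrogate variable (5.55e-04), in a range up to 0.863, the value with an estimated correlation. The direction was up without hydrogel replicate 3 (adjusted p = 0.291) or antimiR-195 replicate 3 (0.755). The 7 tested mitochondrially encoded mRNAs had a median of -0.17 with an adjusted p of 0.0524. They were called lower without antimiR-195 replicate 3 (adjusted p = 0.0360), antimiR-195 replicate 4 (0.0294) or hydrogel replicate 1 (0.0327), and with camera on ranks (0.0219) or upper-quartile factors (0.0466), in a range from 0.0219 to 0.807, with adjusted p = 0.613 with an estimated correlation. Without antimiR-195 replicate 2 their median was -0.01 and the adjusted p 0.807, and with the length trend also removed the direction was up (0.639). Medians and adjusted p were -0.02 and 0.991 for glycolysis and hypoxia, where Bnip3 was at -0.31 ± 0.14, and 0.05 and 0.529 for cyclins and their kinases and inhibitors. They were -0.02 and 0.991 for p53 targets and 0.20 and 0.222 for immediate early genes, which were called higher without antimiR-195 replicate 4 (adjusted p = 0.00269) or hydrogel replicate 2 (0.00532), in a range up to 0.954, with adjusted p = 0.834 with an estimated correlation. Their direction was down without antimiR-195 replicate 1 (adjusted p = 0.738).

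Cell type lists other than those above were not called with all 8 libraries in the main test. Fibroblast identity genes had a median of -0.04 and an adjusted p of 0.222, endothelial genes -0.02 and 0.66, and pericyte and smooth muscle genes 0.08 and 0.222. Neutrophil genes had a median of 0.37 and an adjusted p of 0.0635, with S100a9 at 0.67 ± 0.47, and T and NK cell genes 0.25 and 0.312. Epicardial and mesothelial genes had a median of -0.28 and an adjusted p of 0.794, with the keratins Krt8 at -1.04 ± 0.39 and Krt18 at 0.65 ± 0.55. Medians and adjusted p were 0.01 and 0.448 for atrial, 0.10 and 0.367 for erythroid, and 0.02 and 0.906 for Schwann cell and neuronal genes. The atrial median was 0.31 without antimiR-195 replicate 1 and -0.34 without antimiR-195 replicate 4. Without 1 library, camera with the preset correlation called neutrophil genes higher without hydrogel replicate 4 (adjusted p = 0.00839), antimiR-195 replicate 3 (0.0323) or antimiR-195 replicate 4 (0.0294), and erythroid genes higher without hydrogel replicate 2 (0.00393) or hydrogel replicate 3 (0.0222). Neutrophil genes were also called higher with at least 10 counts in every library (0.0174) or with camera on ranks (0.0484). It called fibroblast identity genes lower (0.0262) and epicardial and mesothelial genes lower (0.00180) without hydrogel replicate 1. The adjusted p of these lists reached 0.830, 0.942, 0.912 and 0.981 over their alternatives, and with an estimated correlation the adjusted p = 0.602, 0.834, 0.788 and 0.922. Without antimiR-195 replicate 2 the direction of the neutrophil list was down, with a median of -0.08, an adjusted p of 0.807 and S100a9 at -0.18, and that of the erythroid list was down, with a median of -0.39 and an adjusted p of 0.759. The erythroid direction was also down without hydrogel replicate 1 (adjusted p = 0.493) or hydrogel replicate 4 (0.873). The epicardial direction was up without hydrogel replicate 3 (0.521), hydrogel replicate 4 (0.832) or antimiR-195 replicate 3 (0.897). T and NK cell genes were called higher only with no filter, at adjusted p = 0.0350 in a range up to 0.602, the value with an estimated correlation, and their median was -0.13 without antimiR-195 replicate 2. The direction of the camera test was opposite to the sign of the median in the sarcomere, glycolysis, p53, macrophage, atrial and Schwann cell lists, and the endothelial list had a positive mean with a negative median and test. Globin genes such as Hba-a1, at 0.21 ± 0.53, have near-identical copies and are uncertain. Skeletal muscle, adipocyte and lung epithelial genes had 3, 3 and 1 members above the filter and were not tested; Tnnt3, Fabp4 and Ager were at 0.56 ± 0.53, 0.20 ± 0.23 and -0.36 ± 0.38. Without antimiR-195 replicate 2 Krt18 was at -0.37, Hba-a1 at -0.35, Tnnt3 at -0.21, Fabp4 at -0.03 and Ager at -0.81.

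Tissue composition was gauged only by a score of gene lists, which varied between libraries of both groups. In the antimiR-195 group the spread came from replicate 2, with the others at -0.375 to -0.116. The composition score, which is higher where matrix and macrophage genes are high and sarcomere genes low, ranged from -1.37 to 1.29 in the hydrogel group and from -0.375 to 1.46 in the antimiR-195 group. The group difference was 0.375 and the exact permutation p was 0.486. Without antimiR-195 replicate 2 the difference was -0.0982. The first principal component held 51.1% of the variance and did not separate the groups, with an exact permutation p of 0.743. It was 63.1 in antimiR-195 replicate 2 and lay between -27.1 and 4.84 in the other 7 libraries. That library had 9.42% of its gene counts in mitochondrially encoded genes, against 16.9% to 22.4% in the others, and 3.14% in ribosomal protein genes against 1.28% to 1.84%.

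**Figure D3:**
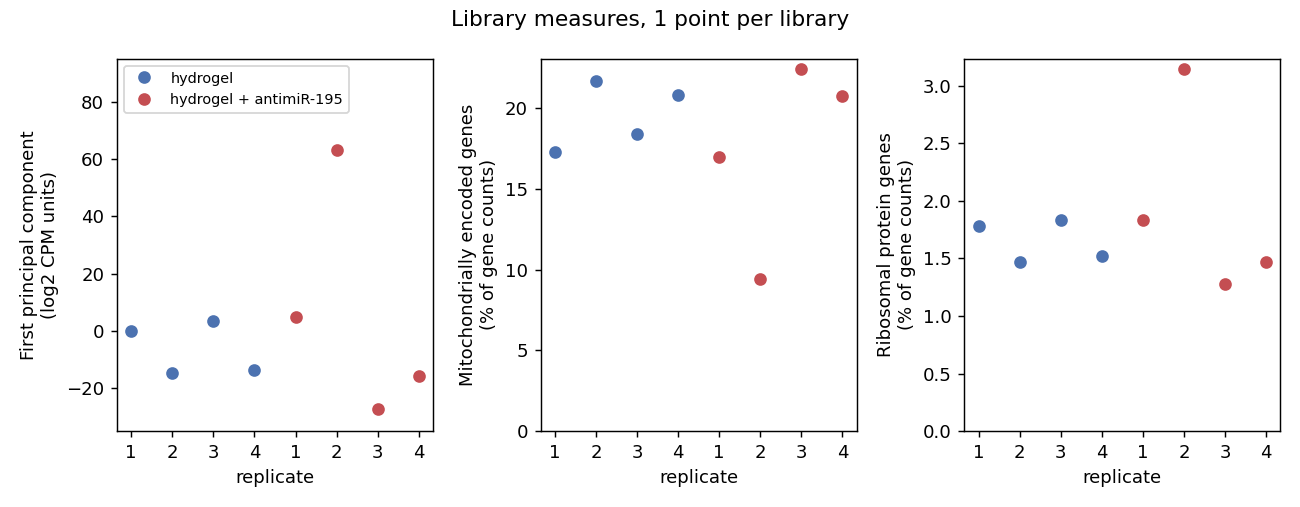
The first principal component of log2 CPM, the share of gene counts in mitochondrially encoded genes and the share in ribosomal protein genes (y axes), with 1 point per library by group and replicate (x axis). AntimiR-195 replicate 2 stands apart from the other 7 libraries in all 3 panels, at 63.1, 9.42% and 3.14%.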

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

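The tests of tissue share, of short-lived transcripts, of the drug, of macrophages of all kinds, of the resident list call with the length trend removed, of replicate 2 in the list calls and of splits for the list and gene counts were chosen only after the result was seen; the length trend removal itself was added after the data were seen, with the bounds of its other 3 tests written before their results, and the test of chance among lists was set before its result. In groups of 4 libraries a library was singled out when its gap to the nearest other library, as a share of the range of the group, exceeded Dixon's 95% critical value. This happened in 15 of 294 groups of values, and chance alone gives about 1 in 20 groups, or 14.7 here. Of the 15, 9 were in antimiR-195 replicate 2.

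In antimiR-195 replicate 2, Pln was at 4588 CPM against 6173 to 6440 CPM in the other 3 antimiR-195 libraries, Lyve1 at 9.19 against 15.7 to 16.9, Slc16a3, a lactate exporter, at 24.0 against 7.40 to 10.1, and Tagln, a smooth muscle gene, at 151 against 52.7 to 69.3. Krt18 was at 12.8 against 1.82 to 3.31 CPM, Tnnt3 at 8.10 against 1.99 to 2.24 and Irf7 at 46.3 against 26.5 to 28.8. The interferon response list had a mean log2 CPM of 4.59 in it against 4.00 to 4.06, and its tissue composition score was 1.46 against -0.375 to -0.116. In hydrogel replicate 1, Cnn1 was at 4.50 CPM against 2.86 to 2.98 in the other hydrogel libraries, and Cfd at 1.01 against 1.99 to 2.10. Tnf was at 0.831 CPM in hydrogel replicate 2 against 0.611 to 0.646. The sarcomere list had a mean log2 CPM of 11.36 in hydrogel replicate 4 against 11.47 to 11.49. In antimiR-195 replicate 4, Slc4a1 was at 0.399 CPM against 0.658 to 0.711 and the Schwann cell and neuronal list at 1.33 against 1.59 to 1.63.

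AntimiR-195 replicate 2 stood apart from the other 7 libraries across the transcriptome, with short genes higher, but after a trend with gene length was removed from every library the SD of its gene deviations was still 1.80 times the highest of the others, against 1.77 times before, which argues against length bias as the whole cause. For a larger share of infarct, a first test, the Pearson r of the composition score with the first component over the other 7 libraries, decided nothing (r -0.319, exact permutation p = 0.580, Spearman rho 0.0357, exact permutation p = 0.963, and r 0.468 without the 2 farthest), and a second was then chosen. The second test assumed that a larger share of infarct lowers mitochondrially encoded mRNAs and nuclear oxidative phosphorylation genes together. The former lay only 2.66 above the latter on the log2 scale in this library and 3.62 to 4.21 above in the others. The assumption was not borne out between hydrogel replicates 3 and 4, with composition scores of -1.37 and 1.29. Their nuclear list means were 10.01 and 9.51, but both mitochondrial list means were 13.64. The length trend was not removed either, so this test does not decide about infarct share. AntimiR-195 replicate 2 also had the highest composition score, 1.46, and the lowest sarcomere list mean, 11.31 against 11.36 to 11.50. A larger share of infarct, alone or beside another cause, therefore stays open. The other 3 antimiR-195 libraries had a mean of -12.7 on the first component, with a range of -27.1 to 4.84. It differed from the hydrogel mean of -6.27 by -6.39 ± 10.4 (SE, exact permutation p = 0.571), when replicate 2 lay 69.3 above the hydrogel mean. A drug effect of that size was therefore not shared by all 4 libraries. This largely restates that replicate 2 stood apart on this component, and a smaller shared shift stays open. Loss of short-lived transcripts stays open, with zinc finger genes at -0.260 on the log2 scale in replicate 2 against -0.0458 or more in the others. Immediate early genes were not lowest in it, but their mean, unlike the zinc finger value, was not adjusted for gene length or level. An uneven response of 1 mouse to the drug may remain and was not tested. Other causes, technical ones included, were not tested either.

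The resident macrophage list separated the groups fully, and chance could not be excluded: in 16 of the 35 splits of the 8 libraries into groups of 4, the real split included, at least 1 of the 27 lists was separated as fully, and up to 5 lists were in splits other than the real one. Whether the antimiR-195 group had a smaller share of remote tissue could not be decided. With the composition score in the model the group difference was -0.29 (exact permutation p of 0.0286), close to -0.34 without it. But the score differed between the groups by only 0.375, so the model could move the group difference little. The score is also partly built from macrophage genes. Fewer macrophages of all kinds remain possible, since the difference between the resident and the broader macrophage list was -0.34 between the groups with an exact permutation p of 0.314, and camera called the broader list lower too without antimiR-195 replicate 2 (adjusted p = 3.70e-05) or hydrogel replicate 3 (0.0154), in a range up to 0.894 over its alternatives. With the length trend removed the difference was -0.36, so it did not shrink. Camera with the preset correlation still called the list (adjusted p = 1.65e-08, in a range of 5.87e-09 to 0.083 over its alternatives). Calls with the preset correlation were frequent in arbitrary splits too, so this call decides nothing about length bias. The SD of the antimiR-195 libraries went from 0.11 to 0.25 and the groups then overlapped. The exact permutation p of 0.0571 missed the bound of 0.05 written beforehand, so length bias was not excluded. No test here separated an effect of antimiR-195 on these genes from chance.

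For the 8 lists called with the preset correlation, chance could not be excluded: 14 of the 35 splits called 8 or more lists, and the highest of the other splits called 13. Without antimiR-195 replicate 2, 5 of the 8 lists were still called, and with the length trend removed 7 were. Since arbitrary splits often gave as many calls, the calls that stayed do not decide about either cause. Neither that library nor length bias was excluded.

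For the count of genes called the splits could decide nothing, because the real split called 0 genes and any split, 35 of 35, then gives as many. At unadjusted p below 0.05 in edgeR's quasi-likelihood test the real split had 178 genes and the other splits 97 to 3810. The real grouping thus lay within the range of arbitrary ones. The highest of the other splits called 5.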

How the results depend on the processing

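The length corrections were alternatives added after seeing the data. No paired analysis was possible because the labels give no numbers shared between the groups. The count of 0 genes held in all 23 alternatives, including DESeq2, limma and the 8 fits without a library, with 93 to 428 genes at unadjusted p below 0.05 and a smallest adjusted p of 0.781. Camera called 0 of 27 lists with an estimated correlation, in place of 8 with the preset 0.01. Under the other settings, single libraries left out included, it called 7 to 11 lists. The matrix, interferon, resident macrophage and both cell division lists were called in all of them, while the stress list was called in 12 of 17, the cytokine list in 16 of 17 and the B cell list in 7 of 16. The composition score, a covariate in 1 of these settings, is itself partly built from the matrix list. Over these settings the adjusted p of camera reached 0.00261 for the matrix, 0.00126 for the interferon, 1.55e-04 for the resident macrophage, 0.0089 for the DNA replication and 0.0482 for the mitosis list. Of the 19 lists not called with all libraries, 10 were called under at least 1 alternative, 9 of them without 1 library. The adjusted p ranged from 1.61e-05 to 0.575 for the stress, 1.31e-05 to 0.279 for the cytokine and 0.00342 to 0.661 for the B cell list. The seed site shift reversed to -0.0139 without the covariates and to -0.00132 in genes with a mean log2 CPM of at least 3; the cause was not tested. Without single libraries it ranged from -0.00129 to 0.00947, and no setting had a p below 0.05. The composition score difference ranged from -0.0982 without antimiR-195 replicate 2 to 0.857 without hydrogel replicate 4. Of 2221 values of the 113 named genes under alternatives, 2199 lay within 1 SD of the main value, and 18 of the 22 others were on an RPKM scale. That SD is the spread between libraries, a wide bound within which a sign can turn. S100a9, for example, went from 0.67 to -0.18 without antimiR-195 replicate 2, so the bound does not show that values were stable. At these depths the counting error is largest for genes near 1 CPM, such as Tnf.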

Other observations

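All tests in this part were chosen only after the result was seen. Genes of the daily clock differed between libraries of the same group. Arntl, the activator of the clock, ranged from 1.89 CPM in hydrogel replicate 3 to 18.3 CPM in hydrogel replicate 2, and Dbp, which peaks in the opposite phase, was 194 and 50.3 CPM in the same libraries. Across the 8 libraries, log2 CPM of Arntl and the mean log2 CPM of the 6 genes Dbp, Per2, Per3, Tef, Ciart and Hlf had a Pearson r of -0.878 (exact permutation p = 0.00151) and a Spearman rho of -0.881 (exact permutation p = 0.00724). Without the 2 libraries farthest from the median of Arntl, r was -0.824 (exact permutation p = 0.0153). This was the only relation of clock genes tested, and a candidate explanation is that hearts were taken at different phases of the day. Wee1, a listed miR-195 target that the clock also drives, ranged from 1.15 to 9.21 CPM.

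Transcripts typical of liver were present at low levels in 7 libraries and lower or without counts in 1. Alb ranged from 3.53 to 16.9 CPM in the other libraries and had 0 counts in antimiR-195 replicate 2, at least 21.5-fold below the lowest of them by a floor of 3 counts, which covers counting error only. Gc, Fgb and Mup3 also had 0 counts there, while Apoa1 had 4 counts, 0.219 CPM against 1.03 to 4.03 in the others, and Ttr 9 counts, 0.492 CPM against 0.854 to 2.72. Malat1, a long nuclear RNA, was at 705 CPM in that library against 2024 to 3458. Loss of short-lived transcripts before freezing was tested as an explanation for that library. The difference of 309 zinc finger genes from genes of like length and level was -0.260 on the log2 scale in it and -0.0458 to 0.136 in the others, which is in line with such a loss. Immediate early genes, which are also short-lived, were not lowest in it, at a mean log2 CPM of 4.06 against 3.54 to 4.33. Unlike the zinc finger value, that mean was not adjusted for gene length or level, so it does not count against such a loss. The explanation stays open.

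Gene length moved with the library in both groups. Across genes within each library, the Spearman correlation of the deviation from the other libraries with gene length ran from -0.456 in antimiR-195 replicate 2 and -0.327 in hydrogel replicate 3 to 0.335 in hydrogel replicate 4 and 0.545 in antimiR-195 replicate 3; genes are not independent replicates.

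By a rule chosen after the values were seen, 4 genes with a mean of at least 2 CPM had 1 library at least 8-fold from the nearest other library: Alb and Zfp955a in antimiR-195 replicate 2, Zmat1 in antimiR-195 replicate 1 and Gt(ROSA)26Sor in hydrogel replicate 4. Zfp955a had 1 count there and 28 or more in every other library. Zmat1, on the X chromosome at 134971372 to 135009209, had 8 counts in antimiR-195 replicate 1 and 126 or more in every other library, while its neighbour Armcx2 had 204 to 307 counts in all libraries. Gt(ROSA)26Sor, the non-coding RNA of the Rosa26 locus on chromosome 6 at 113067428 to 113077333, had 1 count in hydrogel replicate 4, 39 in antimiR-195 replicate 4 and 90 to 168 in the other 6 libraries. Its neighbours Thumpd3 and Setd5 were at 17.2 to 24.3 and 24.3 to 45.3 CPM in all 8 libraries. The gene overlaps the end of Thumpd3, so its reads depend on the unknown strand setting. The Rosa26 locus is widely used for inserted transgenes, and the labels name none; no explanation was tested.

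Of the 13 mitochondrially encoded mRNAs, 6 (mt-Co2, mt-Co3, mt-Atp6, mt-Atp8, mt-Nd3 and mt-Nd4l) had at most 8 counts in any library, while the other 7 had 1061 or more. The list of mitochondrially encoded mRNAs was tested on those 7, and why the others had so few counts was not tested.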
